A study of Mus musculus with 4 samples.

How the data were processed

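RNA-seq libraries from mouse bone marrow cells sorted as pro-B cells were compared between 2 groups, wild type (replicates 1 and 2) and Whsc1-/- (replicates 1 and 3). Per the labels, fetal liver blood-forming cells of either genotype were transplanted into irradiated Rag1-deficient recipients, and donor-reconstituted marrow was sorted as B220+ CD19+ c-Kit+ CD25- live cells. The labels call the 2 libraries of each group independent biological replicates. Libraries were made with SMART-seq2, a full-length method that primes on poly(A) tails and amplifies the cDNA. Per the labels' protocols, 3.2 to 30.6 ng of RNA entered cDNA synthesis, the cDNA was amplified over 20 cycles, the tagmented library over 12 more, and reads were 101 bases long and paired. This kind of library does not mark the strand, so reads from the shared stretch of overlapping antisense genes, such as Xist and Tsix, cannot be told apart.

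The deposited expression table holds normalised counts, treated here as a signal that is never negative, for 47643 genes. The authors' processing, per the submitters' processing notes, used STAR 2.5.1b, RSEM 1.2.28 and DESeq2 1.10.1, and the notes name the builds GRCm38 and mm9. The role of each tool and build is not given in the sources used here. Each library's deposited values were whole multiples of 1 step, as whole reads divided by 1 size factor would be. With a tolerance of 0.1 read, 100% of the values above 0 came out whole in each library, so reads were recovered by multiplying by the size factor. Size factors were 0.856 and 1.42 for the wild-type libraries and 0.600 and 1.48 for the Whsc1-/- libraries. The authors' deposited comparison table gives log2 fold changes, a test score (the Wald statistic in DESeq2's naming), p-values and adjusted p-values per gene, per the file headers. Its mean values equal the means of the 4 deposited libraries within 0.00456. The deposited enrichment tables give, per the file headers, a p-value and a fold enrichment (a ratio of shares) per gene ontology term and per KEGG pathway. The gene list behind them is not stated in the sources used here. All 667 genes matched to a listed ontology term, and all 266 matched to a listed pathway, had an adjusted p under 0.05 in the authors' deposited comparison. The backgrounds held 16609 and 7708 genes. No per-sample column was left unused.

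Recovered reads numbered 58599519 and 50702744 in the wild-type libraries and 53585878 and 50332639 in the Whsc1-/- libraries. A count of 0 allows up to 3 reads, which is 3.51 and 2.12 normalised counts in the wild-type libraries and 5.00 and 2.03 in the Whsc1-/- libraries. These limits, and the 95% Wilson intervals of read shares, cover counting error only, since amplified reads are not independent molecules. Replicates differed by far more than sampling noise, with a chi-square per degree of freedom of 397 between the wild-type libraries and 1369 between the Whsc1-/- libraries, so each was counted as its own sample.

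Because the deposited values are normalised, the main test was limma 3.58.1 in R 4.3.3 on log2(normalised count + 1), with an intensity trend in the prior, for 15882 genes with a mean of at least 10. Fold changes are therefore on the log2(value + 1) scale, which understates changes of low genes. P-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 counted as changed. Gene lists, 38 in number, were fixed before the data were examined, as were the tests of genes, lists and V segments and their alternatives, except 1 alternative for the V segments. That alternative, and the tests of explanations other than that of X-linked genes, were written after values were seen. Lists with at least 5 tested members, 37 of them, were compared with all other tested genes by camera with a preset correlation of 0.01, adjusted over the lists. Counts of changed members are given over all genes tested and "adjusted over the list alone". With an estimated correlation no list passed in camera (smallest adjusted p = 0.196), and that p is printed beside each list called. The ratio of distal to proximal heavy-chain V segments was compared by an exact two-sided permutation test, which cannot go below 0.333 with 2 libraries against 2.

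Genes were named by a rule fixed beforehand. Whsc1 is always given. Then follow the 8 genes that rose and the 8 that fell with the largest log2 changes among genes with an adjusted p under 0.05, a mean of at least 50 and both Whsc1-/- libraries on 1 side of both wild-type libraries. Unnamed gene models and antigen receptor segments are passed over. In each list, up to 4 changed members with the smallest p are given, or up to 2 members as values if none changed, and abundant markers are added for lists of other cell types. Any other gene was chosen after its values were seen. Coordinates come from GENCODE M21 on GRCm38 by Ensembl identifier, which matched 99.1% of rows.

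Alternatives were pseudocounts of 0.5 and 8, no filter and a mean of at least 50, TMM, upper-quartile and total-count scaling (the total leaving out immunoglobulin, ribosomal protein and mitochondrial genes), limma without trend or with a robust prior, each library left out in turn, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. An adjusted p under 0.1, a log2 change of at least 1, camera on ranks, fry and other definitions of the V segment ratio were also tried. edgeR called 170 genes and DESeq2 1264 on the recovered reads. Python 3.11.15 with scipy 1.17.1 was used for summaries.

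The tests were checked on simulated data for the Whsc1-/- against wild-type comparison, in 10 simulations with 200 changed genes each, 50 per fold size, drawn from genes with a mean of at least 50. The limma test, on 14832 simulated genes passing the filter, recovered 0.8%, 8.6%, 47.2% and 83.6% of genes changed by 1, 2, 3 and 5 on the log2 scale, and 13.2% of its calls were false. On 15882 genes, edgeR recovered 1.0%, 12.0%, 53.6% and 87.4% with 17.2% false calls, and DESeq2 3.2%, 30.0%, 72.6% and 96.4% with 48.4% false calls. On simulated data the camera p-value was 1.59e-21 for a list of 30 shifted genes and 0.929 for a list of 30 unshifted genes. Simulated genes were drawn independently of each other, so these values do not check the preset correlation on which the list calls depend. Each of limma, edgeR and DESeq2 thus made more false calls in simulation than the 0.05 threshold states.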

Results

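Gene expression was measured by RNA-seq in marrow cells of mice carrying wild-type or Whsc1-/- blood cells, sorted by a gate for pro-B cells, early B-lineage precursors, with 2 libraries per group. The comparison was between sorted Whsc1-/- and wild-type cells. Some transcripts of the B lineage were nearly absent from Whsc1-/- replicate 1, with Cd19 at 0.255% and Ebf1 at 0.127% of the wild-type mean. Others were low but less reduced in that library, with Dntt at 2.08% and Ighm at 5.11%. Its median log2 difference from the wild-type mean was -3.81 for the pre-B cell receptor list and -2.25 for B-lineage transcription factors. The comparison therefore does not show which genes depend on Whsc1 in pro-B cells. Depth was even, at 50332639 to 58599519 recovered reads per library, but genes with at least 1 read numbered 22734 and 20088 in the wild-type libraries and 16754 and 18882 in Whsc1-/- replicates 1 and 3. Across genes, which are not independent replicates, Spearman's rho was 0.954 between the wild-type libraries and 0.867 between the Whsc1-/- libraries, against 0.808 to 0.885 between groups.

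In the Whsc1-/- libraries, gene lists of B cell identity were lower and lists of myeloid markers and of antigen presentation were higher than in the wild type. The median log2 change was -2.83 over 22 genes of the pre-B cell receptor and its signalling, -6.02 over 60 light-chain segments and constants, and -1.75 over 36 genes of mitosis. It was 3.79 over 17 monocyte and macrophage markers and 3.51 over 13 genes of MHC class II presentation. These lists passed with a preset correlation among their genes, and none of the 37 lists tested passed with an estimated one. The Whsc1-/- libraries also differed from each other, as the granulocyte transcript S100a8 stood at 2386499 normalised counts in replicate 1 and 1359 in replicate 3.

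Whsc1 (also named Nsd2; ENSMUSG00000057406.16; GRCm38 chromosome 5, 33820725 to 33897975, plus strand), which encodes a histone H3 lysine methyltransferase, had 5986 and 8155 normalised counts in the wild-type libraries. It had 1640 and 3832 in Whsc1-/- replicates 1 and 3. Both Whsc1-/- libraries were thus below both wild-type libraries, with a log2 change of -1.48 ± 0.54 (SE, n = 2 per group), but the gene did not pass the limma test (adjusted p = 0.293). The transcript was not absent in either library. The labels do not say which part of the gene the allele lacks, so these gene-level values do not check the genotype.

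Xist, the non-coding RNA of X inactivation (chromosome X, 103460366 to 103483254), had 7358 and 4574 normalised counts in the Whsc1-/- libraries, against 7.01 and 0 in the wild-type libraries (limma adjusted p = 0.0181, edgeR adjusted p = 0.0184). With 1 library left out the log2 change ran from 9.50 to 12.50, and the call was lost each time (adjusted p = 0.0739 to 0.99998). Mefv, the gene of the inflammasome protein pyrin (chromosome 16, 3707218 to 3718097), had 1395 and 542 normalised counts against 1 read in wild-type replicate 1 and none in replicate 2. From pooled reads its ratio was 1791 with an exact 95% counting interval of 321 to 70768. Cd300lb, a myeloid immunoglobulin-like receptor (chromosome 11, 114922781 to 114934386), had 492 and 589 against no read in either wild-type library, at least 192-fold higher when the floor of 3 reads is taken per library. Tgfbi, a secreted matrix protein, had 1782 and 1156 against 8.18 and 0 (log2 change 8.89 ± 1.32). Ccl9, a chemokine, had 12910 and 2550 against 30.4 and 42.4 (7.28 ± 0.79). Emilin2, a matrix glycoprotein, had a mean of 2413 in the Whsc1-/- libraries against 15.5 in the wild type (7.26 ± 0.68). Lilra6, a leukocyte receptor of a family with similar copies whose reads may be shared, had 498 and 1425 against 3.51 and 2.83, and the potassium channel gene Kcnk12 had 912 and 670 against 5.84 and 2.83.

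Among genes that fell, Jchain, the joining chain of polymeric immunoglobulins (chromosome 5, 88519809 to 88527891), had 80.0 and 13.5 normalised counts in the Whsc1-/- libraries against 15852 and 11548 (log2 change -8.62 ± 0.79, adjusted p = 0.0146). Ctse, the aspartic protease cathepsin E (chromosome 1, 131638306 to 131675505), had 137 and 190 against 36126 and 15040 (-7.17 ± 0.52, adjusted p = 0.00724). Chchd10, a mitochondrial protein gene, had 927 and 1054 against 48845 and 20117 (-4.99 ± 0.55; the call was lost with edgeR, adjusted p = 0.0561). Bok, a BCL2-family gene, had 16.7 and 104 against 2199 and 2332, and the tetraspanin gene Tspan6 had 10.0 and 52.8 against 1812 and 1256. Fxyd6 had 25 in each Whsc1-/- library against 1118 and 803, and Uchl1, a ubiquitin hydrolase gene, had 26.7 and 41.3 against 1130 and 838. Klra4, a receptor of the Ly49 family whose similar members may share reads, had 21.7 and 55.5 against 1355 and 1982.

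**Figure D1:**
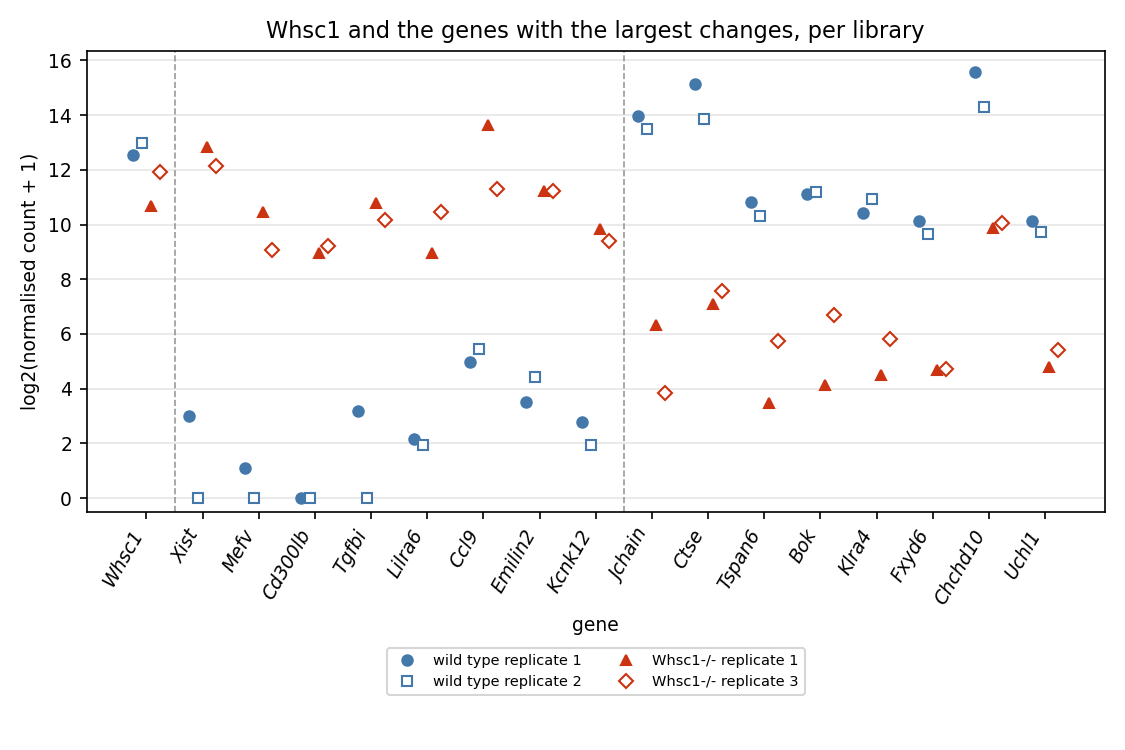
Normalised counts of Whsc1 and the 16 genes with the largest changes in the 4 libraries, on a log2(normalised count + 1) axis, with 1 symbol per library and dashed lines between Whsc1, genes that rose and genes that fell. In each gene both Whsc1-/- libraries lie on 1 side of both wild-type libraries, and Whsc1 itself, at 1640 and 3832 against 5986 and 8155, did not pass the test.

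In all, 139 of 15882 tested genes changed by limma (adjusted p under 0.05), of which 97 rose and 42 fell. Under total-count scaling 158 rose and 145 fell, so the share that rose was 52.1% in place of 69.8%. The groups did not overlap for 3269 genes higher and 3633 lower in Whsc1-/- cells, 43.5% of tested genes where chance gives 33.3%. The count rests on all 4 libraries: without wild-type replicate 1, wild-type replicate 2 or Whsc1-/- replicate 3 limma called 0 genes (878, 646 and 3902 at an unadjusted p under 0.05), and 12 without Whsc1-/- replicate 1. On all 4 libraries edgeR called 170 genes and DESeq2 1264. Of the 36 called genes named here, 8 lost the call with edgeR, 16 with a pseudocount of 0.5, 20 under upper-quartile scaling, all 36 without trend, and none with DESeq2. Without Whsc1-/- replicate 1, 32 lost it.

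B-lineage gene groups were lower in the Whsc1-/- libraries. The pre-B cell receptor list had 15 of 22 members below both wild-type libraries and a median log2 change of -2.83. Of its members, 1 fell over all genes, and 13 fell and 1 rose adjusted over the list alone. The list fell in camera (adjusted p = 3.92e-06; adjusted p = 0.474 with an estimated correlation). The called member was Cd79b, a signalling chain of the B cell receptor, with 908 and 2988 normalised counts against 65193 and 30694 (log2 change -4.76 ± 0.73, limma adjusted p = 0.0432). That call was lost with edgeR (adjusted p = 0.117), under upper-quartile scaling (0.0802) and with a pseudocount of 0.5 (0.0553). The list of B-lineage transcription factors fell as well (median -1.44, adjusted p = 0.000345; adjusted p = 0.539 with an estimated correlation), with 13 of 24 members below both wild-type libraries. Its only called member went the other way: Spi1, the myeloid and B cell regulator PU.1, rose to 22950 and 9658 from 1552 and 868 (limma adjusted p = 0.0448). That call was lost as well with edgeR (adjusted p = 0.0745), under upper-quartile scaling (0.104) and with a pseudocount of 0.5 (0.0577). Adjusted over the list alone, 8 of these factors fell and 2 rose.

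The list of V(D)J recombination and end joining fell (median -1.16, camera adjusted p = 7.90e-05; adjusted p = 0.474 with an estimated correlation). None of its 19 members passed over all genes in limma (7 at an unadjusted p under 0.05) or edgeR, 4 fell in DESeq2 and 4 fell adjusted over the list alone in limma. Dntt, the terminal transferase, had 3360 and 6248 normalised counts against 253753 and 70031, and Xrcc6, the Ku70 gene, had 1472 and 2233 against 12320 and 7604. The list of later B cell stages fell too (median -1.74, adjusted p = 0.00408; adjusted p = 0.539 with an estimated correlation), but not without Whsc1-/- replicate 1 (adjusted p = 0.0988, in a range over the alternatives of 0.000229 to 0.539). Of its 23 members 1 fell over all genes, and 4 fell and 1 rose adjusted over the list alone. That member was Igkc, the kappa light-chain constant region, at 857 and 526 against 92470 and 58956 (log2 change -6.78 ± 0.53, limma adjusted p = 0.00724), a call lost with edgeR (adjusted p = 0.0546).

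The 2 Whsc1-/- libraries differed in how far B-lineage transcripts were reduced, in genes chosen after their values were seen. Cd19, the gene of a surface protein used in the sort, had 71.7 and 2730 normalised counts in Whsc1-/- replicates 1 and 3, which is 0.255% and 9.71% of the wild-type mean. Ebf1 stood at 0.127% and 6.90% of the wild-type mean and Pax5 at 0.217% and 13.2%, both transcription factors of B cell commitment. Vpreb1, part of the surrogate light chain, had 56.7 and 2550 normalised counts against 163310 and 52686. Igll1, a surrogate light chain, stood at 0.0909% and 3.17%. Kit, another gate gene, had 9480 and 3066 against 1933 and 1531, and Ptprc, which encodes B220, had 10760 and 15436 against 12104 and 14065.

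**Figure D2:**
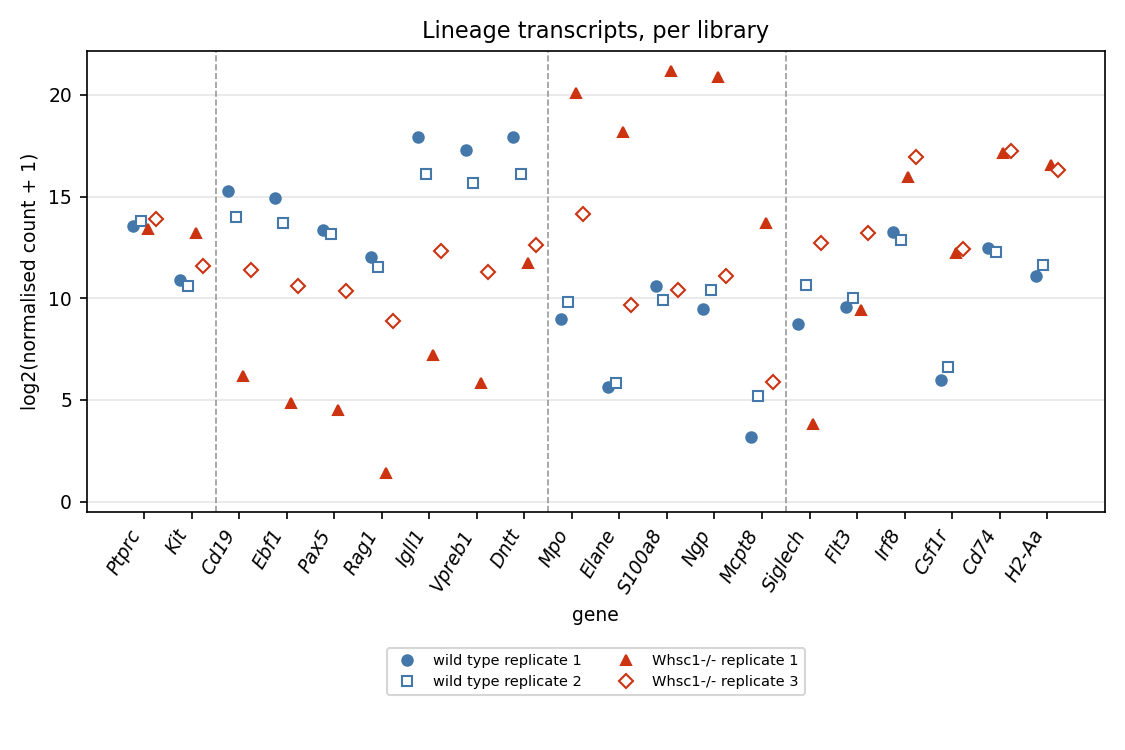
Normalised counts of gate genes, B-lineage genes, granulocyte or basophil genes, and dendritic, monocyte or antigen presentation genes in the 4 libraries, on a log2(normalised count + 1) axis, with 1 symbol per library and dashed lines between the groups of genes, which were chosen after their values were seen. Whsc1-/- replicate 1 is lowest for Cd19 (71.7) and highest for S100a8 (2386499), while replicate 3 is highest for Siglech (6838) and Flt3 (9623).

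Marker lists of myeloid cells were higher in the same libraries. The monocyte and macrophage list rose (median log2 change 3.79, camera adjusted p = 3.16e-11; adjusted p = 0.474 with an estimated correlation), with 6 of 17 members up over all genes and 10 up adjusted over the list alone. Csf1r, the receptor for macrophage colony-stimulating factor, rose to 4832 and 5590 from 63.1 and 96.1 (6.04 ± 0.46, limma adjusted p = 0.00724). Ms4a6c rose to 25448 and 8063 from 68.9 and 156, F13a1 to 21276 and 5986 from 574 and 492, and Cd68 to 1967 and 2564 from 60.8 and 172. Of its abundant members, Lyz2 had 1260761 and 13900 against 5794 and 3866, and Ly6c2 had 718950 and 7091 against 528 and 1123.

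The neutrophil and granulocyte progenitor list also rose (median 6.12, adjusted p = 9.49e-11; adjusted p = 0.474 with an estimated correlation). None of its 18 members passed over all genes in limma (11 at an unadjusted p under 0.05), 1 rose in edgeR and 14 in DESeq2, and 7 rose adjusted over the list alone in limma. Prtn3, a granule protease, had 144156 and 4493 normalised counts against 32.7 and 120, and Csf3r had 2659 and 268 against 7.01 and 1.41. The most abundant members were far higher in Whsc1-/- replicate 1 than in replicate 3. S100a8 had 2386499 and 1359 against 1572 and 979, Ngp had 1965817 and 2155 against 712 and 1336, and Mpo had 1129070 and 17909 against 502 and 892. The mast cell and basophil list rose (median 3.45, adjusted p = 0.0185; adjusted p = 0.675 with an estimated correlation) but turned downward without Whsc1-/- replicate 1 (adjusted p = 0.941, in a range over the alternatives of 2.83e-06 to 0.941) and did not pass without wild-type replicate 1 (adjusted p = 0.09999) or without trend (0.0726). Its 1 called member of 8, also the 1 adjusted over the list alone, was the cytokine receptor gene Csf2rb, which rose to 6956 and 5161 from 310 and 881, a call lost with edgeR (adjusted p = 0.0600). Abundant members were at 13260 and 58.2 against 8.18 and 35.3 for Mcpt8, and at 21305 and 0 against 21.0 and 7.77 for Prss34.

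The dendritic cell list rose (median 2.29, adjusted p = 0.000163; adjusted p = 0.539 with an estimated correlation), but not without Whsc1-/- replicate 3 (adjusted p = 0.693, in a range over the alternatives of 1.57e-08 to 0.693). None of its 15 members passed over all genes in limma (7 at an unadjusted p under 0.05), 1 rose in edgeR and 7 in DESeq2, and 5 rose adjusted over the list alone in limma. Clec9a had 433 and 2267 against 19.9 and 4.24, Zbtb46 had 642 and 2352 against 78.3 and 118, and the abundant Siglech and Flt3 had 13.3 and 6838 against 421 and 1608, and 685 and 9623 against 772 and 1037. The MHC class II list rose (median 3.51, adjusted p = 3.89e-10; adjusted p = 0.334 with an estimated correlation), with 4 of 13 members up over all genes and 9 adjusted over the list alone. H2-Eb1 rose to 37145 and 29733 from 784 and 890 (5.31 ± 0.44, limma adjusted p = 0.00894). H2-Aa rose to 96281 and 80490 from 2181 and 3238, H2-DMb1 to 10945 and 12063 from 220 and 634, and H2-DMa to 17916 and 14104 from 1164 and 1671. The calls of H2-Aa (adjusted p = 0.108) and H2-DMa (0.0600) were lost with edgeR.

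The remaining marker lists of other cells did not pass. The erythroid list, given next, passed upward without Whsc1-/- replicate 3 (adjusted p = 8.86e-05), under total-count scaling (0.0333) and with DESeq2 (0.00560), and turned downward without replicate 1 (adjusted p = 0.0988, in a range over the alternatives of 8.86e-05 to 0.924). The erythroid and megakaryocyte list (16 members, adjusted p = 0.174) had Itga2b at 813 and 31.8 against 15.2 and 7.06, Car1 at 25283 and 113 against 79.5 and 74.9, and the abundant Hba-a1 at 425 and 28.4 against 76.0 and 283. Of the T and NK cell list (20 members, adjusted p = 0.152), Klrb1c had 73.3 and 720 against 2180 and 3105, Gzma had 73.3 and 310 against 435 and 1056, and Cd3e had 140 and 0 against 5.84 and 11.3. In neither list did a member pass over all genes or adjusted over the list alone in limma (0 and 4 at an unadjusted p under 0.05). No member passed in edgeR, while DESeq2 called 2 up in the erythroid list and 1 up and 1 down in the T and NK cell list. The plasma cell list (10 members, adjusted p = 0.137) had 1 called member, Jchain, and 2 members up and 2 down adjusted over the list alone. It passed downward under total-count scaling (adjusted p = 0.000504), with edgeR (0.0436) and with DESeq2 (0.0130), in a range over the alternatives of 0.000504 to 0.585. The stromal and endothelial list (5 members, adjusted p = 0.986) had no member called by limma (0 at an unadjusted p under 0.05), edgeR or DESeq2, with Kdr at 0 and 33.8 against 56.1 and 24.7 and Pecam1 at 1700 and 3504 against 1727 and 2358.

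**Figure D3:**
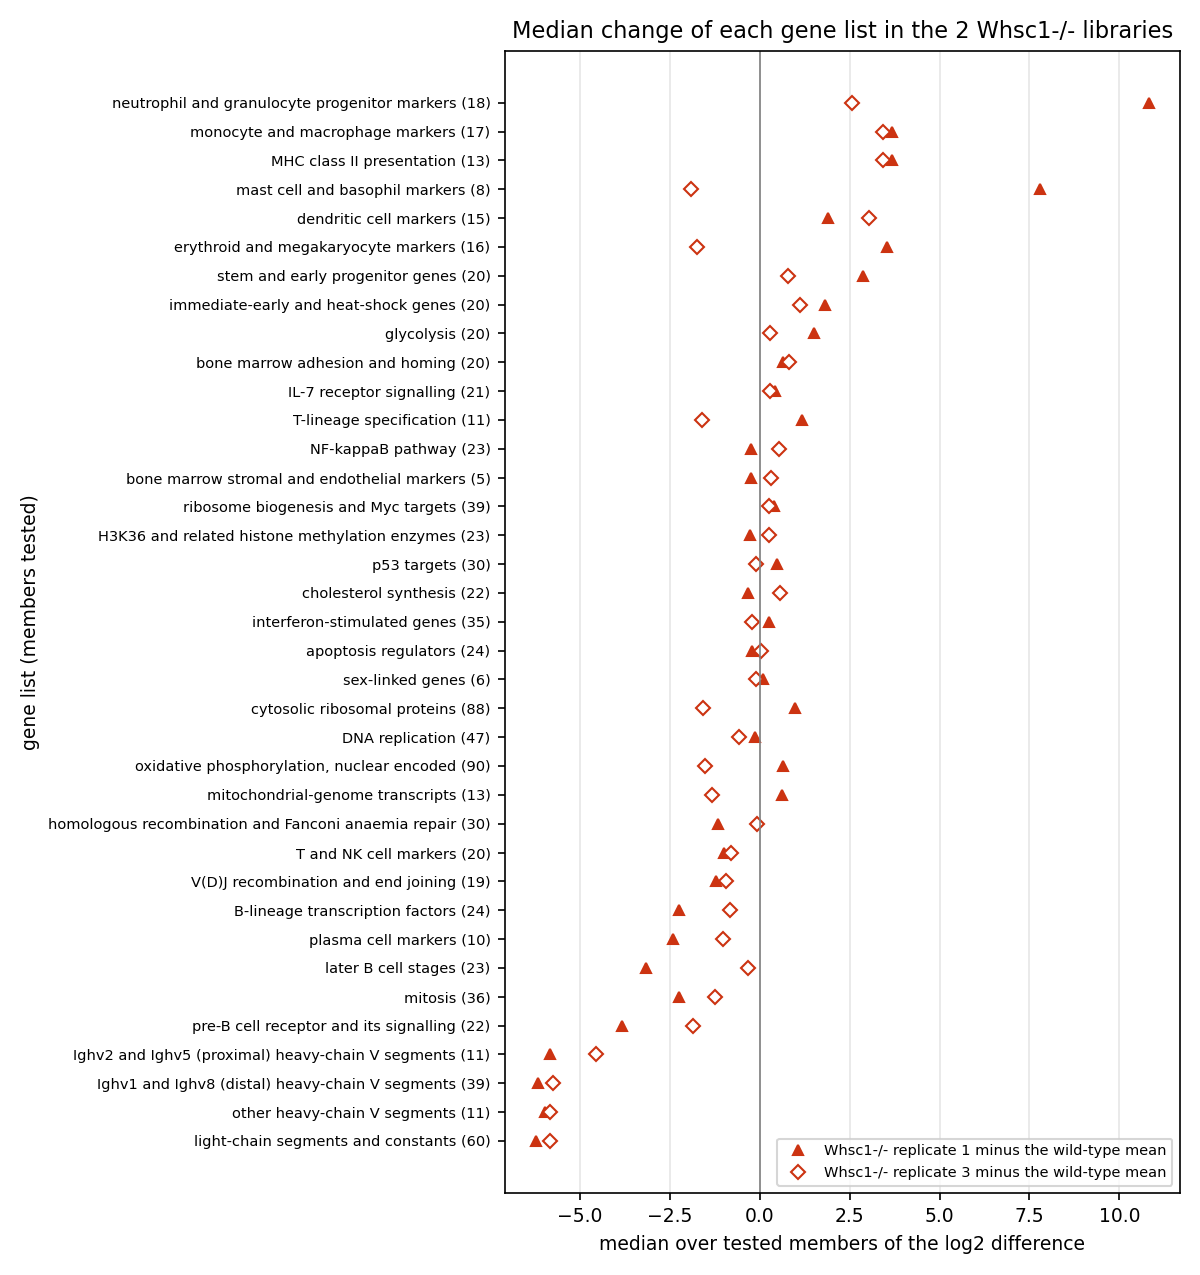
Median over the tested members of each gene list (number in brackets) of log2(normalised count + 1) in each Whsc1-/- library minus the wild-type mean, with 1 symbol per Whsc1-/- library. The neutrophil list stands at 10.82 in replicate 1 and 2.57 in replicate 3, and the mast cell and basophil list at 7.80 and -1.90, while the light-chain list stands at -6.22 and -5.82.

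Immunoglobulin segments, whose similar sequences may share reads, were low, and immunoglobulin genes made up 0.700% and 0.701% of reads in the wild-type libraries but 0.0150% and 0.0815% in Whsc1-/- replicates 1 and 3. The light-chain list fell (median log2 change -6.02, or -4.98 with the 38 members that had a group at 0 set to their bound). Its camera adjusted p was 7.69e-26 (adjusted p = 0.196 with an estimated correlation). Of its 60 members 6 fell over all genes and 32 fell adjusted over the list alone. Besides Igkc, Igkv6-20 had 8.33 and 2.71 against 2194 and 2425, Iglc1 had 0 and 2.71 against 802 and 1915, and Igkv6-15 had no read against 4821 and 1354, at least 878-fold lower. The distal heavy-chain V list fell (median -5.71, or -4.53 with 33 members at their bound, adjusted p = 4.50e-20; adjusted p = 0.334 with an estimated correlation), with 2 of 39 members called and 20 adjusted over the list alone. Those were Ighv1-55 and Ighv1-26, with no read in Whsc1-/- cells, at least 411-fold and 262-fold lower. The proximal list fell (median -5.12, or -4.52 with 4 members at their bound, adjusted p = 5.42e-05; adjusted p = 0.334 with an estimated correlation), with none of 11 called by limma (7 at an unadjusted p under 0.05) or edgeR, 5 down in DESeq2 and 1 adjusted over the list alone in limma. Ighv2-2 and Ighv2-9-1 had no read against 490 and 70.7, and 79.5 and 82.0. Other heavy-chain V segments fell likewise (median -5.96, or -4.29 with 8 at their bound, adjusted p = 4.60e-07; adjusted p = 0.334 with an estimated correlation), with none of 11 called by limma (7 at an unadjusted p under 0.05), 2 down in edgeR, 7 in DESeq2 and 7 adjusted over the list alone in limma. Ighv14-4 had no read against 398 and 351, and Ighv11-2 none against 162 and 502. None of the 24 heavy-chain D and J segments reached the filter.

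Reads from distal V segments, as a share of distal plus proximal reads, were 89.4% (95% Wilson interval 88.8 to 90.0) and 90.3% (89.6 to 90.9) in the wild-type libraries. They were 40.0% (30.2 to 50.6) in Whsc1-/- replicate 1 and 79.6% (72.6 to 85.2) in replicate 3, from 34 distal and 51 proximal reads and from 125 and 32. The log2 ratio of distal to proximal normalised counts was 3.08 and 3.21 in the wild type and -0.58 and 1.97 in Whsc1-/- cells. The difference of the means was -2.46 (exact two-sided permutation p = 0.3333, the smallest that 2 libraries against 2 allow). Over the members' log2 changes the difference of medians was -0.45. Such medians do not measure the difference well, since 33 of 39 tested distal and 4 of 11 tested proximal members had a group at 0. The difference of ratios was -1.18 without Whsc1-/- replicate 1 and -3.73 without replicate 3. In replicate 1, Cd19 stood at 0.255% and Rag1 at 0.0464% of the wild-type mean. Its 85 distal and proximal reads therefore do not show V segment use in Whsc1-/- pro-B cells.

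**Figure D4:**
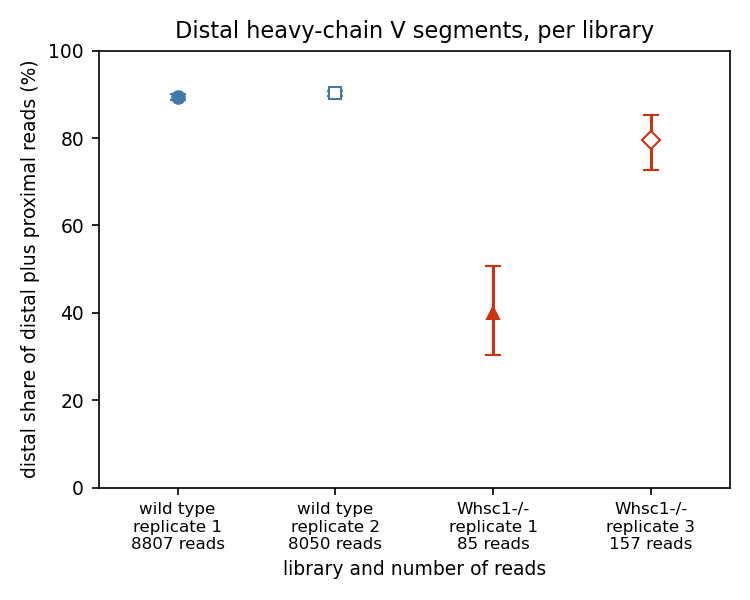
Share of distal reads (Ighv1 and Ighv8 segments) among distal and proximal (Ighv2 and Ighv5) reads per library, in percent, with 95% Wilson intervals that cover counting error only. The wild-type libraries stand at 89.4% and 90.3%, and the Whsc1-/- libraries at 40.0% and 79.6%, on only 85 and 157 reads.

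Cell division genes were lower as a list. The mitosis list fell (median log2 change -1.75, camera adjusted p = 2.53e-16; adjusted p = 0.474 with an estimated correlation), with 33 of 36 members below both wild-type libraries. None passed over all genes in limma (27 at an unadjusted p under 0.05) or edgeR, 10 fell in DESeq2, and 23 fell adjusted over the list alone in limma. Cdc25b, a phosphatase of mitotic entry, had 500 and 1968 against 14429 and 7888, and Hmmr had 1227 and 1382 against 4804 and 3626. The DNA replication list fell by less (median -0.40, adjusted p = 0.0118; adjusted p = 0.783 with an estimated correlation), with none of 47 members called by limma (4 at an unadjusted p under 0.05, none adjusted over the list alone), edgeR or DESeq2. It did not pass without wild-type replicate 1 (adjusted p = 0.606) or without Whsc1-/- replicate 3 (adjusted p = 0.335, in a range over the alternatives of 6.08e-06 to 0.783). Gins2 had 1955 and 1414 against 4321 and 4131, and Rfc4 had 2585 and 1808 against 6266 and 4412. The list of homologous recombination and Fanconi anaemia repair fell (median -0.64, adjusted p = 0.00990; adjusted p = 0.783 with an estimated correlation), with none of 30 members called by limma (2 at an unadjusted p under 0.05, none adjusted over the list alone), edgeR or DESeq2. It did not pass without Whsc1-/- replicate 1 (adjusted p = 0.958), under total-count scaling (0.126) or with DESeq2 (0.0581), in a range over the alternatives of 1.78e-05 to 0.958. Palb2 had 820 and 913 against 393 and 342, and Fancl had 91.7 and 497 against 854 and 999.

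Several other lists rose. Stem and early progenitor genes rose (median 1.59, adjusted p = 0.00149; adjusted p = 0.474 with an estimated correlation), with 1 of 20 called, and 1 adjusted over the list alone. That was Cd34, a progenitor surface protein, at 7184 and 2920 against 86.5 and 49.5 (6.11 ± 0.60, limma adjusted p = 0.0168). Immediate-early and heat-shock genes rose (median 1.41, adjusted p = 4.47e-05; adjusted p = 0.474 with an estimated correlation), with 1 of 20 called and 6 adjusted over the list alone. That member, Hspa1a, rose to 923 and 735 from 35.1 and 31.1 and may share reads with Hspa1b. Glycolysis genes rose (median 0.65, adjusted p = 0.00119; adjusted p = 0.474 with an estimated correlation), though not without Whsc1-/- replicate 1 (adjusted p = 0.0583, in a range over the alternatives of 1.62e-05 to 0.474), with none of 20 called by limma (4 at an unadjusted p under 0.05) or edgeR, 4 up in DESeq2 and 1 adjusted over the list alone in limma. Hk2 had 1030 and 835 against 111 and 138, and Slc16a3 had 250 and 263 against 7.01 and 28.3. Ribosome biogenesis and Myc targets rose (median 0.25, adjusted p = 0.0337; adjusted p = 0.474 with an estimated correlation), with none of 39 called by limma (1 at an unadjusted p under 0.05, none adjusted over the list alone), edgeR or DESeq2. That call was lost under 10 alternatives, among them those without wild-type replicate 1 (adjusted p = 0.0677), wild-type replicate 2 (0.0506) and Whsc1-/- replicate 1 (0.223), in a range of 0.00296 to 0.474. Nop2 had 2257 and 1993 against 1173 and 985, and Srm had 19544 and 4343 against 3572 and 2358. The nuclear-encoded oxidative phosphorylation list fell (median -0.45, adjusted p = 0.0497; adjusted p = 0.924 with an estimated correlation), and turned upward without Whsc1-/- replicate 3 (adjusted p = 0.00117). It did not pass without wild-type replicate 1 (adjusted p = 0.882), with a pseudocount of 0.5 (0.0562), without a filter (0.178), under upper-quartile scaling (0.116), without trend (0.158), with edgeR (0.142) or with DESeq2 (0.481), in a range of 1.41e-14 to 0.924. None of its 90 members was called by limma (1 at an unadjusted p under 0.05, none adjusted over the list alone), edgeR or DESeq2, with Ndufaf3 at 638 and 430 against 1074 and 1211 and Ndufs5 at 3712 and 840 against 6423 and 3335. All of these stand beside the myeloid transcripts above, with S100a8 at 2386499 in Whsc1-/- replicate 1 and Flt3 at 9623 in replicate 3.

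The remaining lists did not pass. Bone marrow adhesion and homing (adjusted p = 0.0790) had 1 of 20 members called, Itgb7, an integrin chain, which rose to 13375 and 30945 from 672 and 1356 (4.41 ± 0.59, limma adjusted p = 0.0351), a call lost with edgeR (adjusted p = 0.0643). Adjusted over the list alone, 6 of its members rose and 3 fell. The list passed upward without a filter on low values (adjusted p = 0.0145, in a range over the alternatives of 0.0145 to 0.474). IL-7 receptor signalling (21 members, adjusted p = 0.199) had none called by limma (5 at an unadjusted p under 0.05, none adjusted over the list alone) or edgeR and 1 down in DESeq2, Il7r, which was at 250 and 1363 against 6460 and 6242, with Stat5b at 3042 and 2262 against 1264 and 1000. The histone methylation enzymes (23 members, adjusted p = 0.986) had none called by limma (3 at an unadjusted p under 0.05, none adjusted over the list alone) or edgeR and 1 down in DESeq2, Ezh2, which was at 2947 and 4155 against 17226 and 10975, with Suz12 at 1407 and 1160 against 3212 and 2802. p53 targets (30 members, adjusted p = 0.986) and apoptosis regulators (24 members, adjusted p = 0.761) each had none called over all genes in limma (7 and 6 at an unadjusted p under 0.05) or edgeR. Each had 1 up and 1 down in DESeq2, and 1 up and 1 down adjusted over the list alone in limma. Trp53inp1 had 970 and 1202 against 5663 and 4360, Bcl2l1 had 427 and 524 against 2997 and 2136, and Pmaip1, in both lists, had 360 and 1443 against 31.6 and 8.48.

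No member was called by limma, over all genes or adjusted over the list alone, or by edgeR in the lists of the NF-kappaB pathway (23 members, adjusted p = 0.340), interferon-stimulated genes (35, adjusted p = 0.871), cholesterol synthesis (22, adjusted p = 0.273), T-lineage specification (11, adjusted p = 0.986), cytosolic ribosomal proteins (88, adjusted p = 0.433) and mitochondrial-genome transcripts (13, adjusted p = 0.761). At an unadjusted p under 0.05 limma had 4, 5, 2, 2, 0 and 0 members of these lists, in that order. DESeq2 called Mx1 up among interferon-stimulated genes, Fdps up in cholesterol synthesis, and Hes1 down and 1 more gene up in T-lineage specification, and none in the other 3 lists. Without Whsc1-/- replicate 1, NF-kappaB (adjusted p = 0.0230) and cholesterol synthesis (adjusted p = 0.00134) passed upward and ribosomal proteins passed downward (adjusted p = 2.47e-06). Under total-count scaling the ribosomal proteins (adjusted p = 1.08e-05) and mitochondrial transcripts (adjusted p = 0.00433) passed downward. The ribosomal proteins also passed downward without wild-type replicate 2 (adjusted p = 0.00494) and upward without Whsc1-/- replicate 3 (adjusted p = 0.00692). Over the alternatives, adjusted p ranged from 0.0230 to 0.929 for NF-kappaB, from 0.00134 to 0.924 for cholesterol synthesis, from 0.00433 to 0.987 for mitochondrial transcripts and from 2.47e-06 to 0.999 for ribosomal proteins. Tnfaip3 had 215 and 520 against 1083 and 1467, and Nfkb1 had 4771 and 8930 against 2538 and 2195. Mx1 had 270 and 856 against 32.7 and 77.0, and Ifi27l2a had 893 and 252 against 1535 and 2247. Fdps had 5761 and 5227 against 1861 and 1830, and Insig1 had 883 and 1181 against 563 and 377. Hes1 had 25 and 116 against 318 and 771, and Zap70 had 168 and 191 against 488 and 744. Rpl3l had 0 and 29.1 against 66.6 and 84.8, Rpl7l1 had 5112 and 2807 against 2559 and 1788, mt-Nd2 had 27095 and 8769 against 26184 and 20616, and mt-Atp8 had 6744 and 2045 against 7863 and 3324. Median and mean differed in sign for T-lineage specification (0.35 and -0.13), apoptosis regulators (-0.09 and 0.04), the histone methylation enzymes (0.13 and -0.06), interferon-stimulated genes (0.01 and -0.17), the stromal list (0.27 and -0.39) and the sex-linked list (-0.09 and 3.28). For p53 targets the median (0.12) and mean (0.14) were above 0 while camera's direction was down.

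The sex-linked list (6 members, adjusted p = 0.0797) had 1 called member, Xist, and 2 up adjusted over the list alone. It passed upward without a filter (adjusted p = 0.0154), under total-count scaling (0.000134), with edgeR (0.00161) and with DESeq2 (0.000336), in a range over the alternatives of 0.000134 to 0.474. Tsix, which overlaps Xist in antisense and extends beyond it (103431517 to 103484957), had 3871 and 278 against 1 read in wild-type replicate 1 and none in replicate 2. Reads from the shared stretch cannot be told from those of Xist, and their part in the Tsix values is not known. Y-linked genes were present in every library. Ddx3y had 1147 and 1360 in the Whsc1-/- libraries against 1374 and 1553, Eif2s3y had 2022 and 1535 against 2434 and 1515, Kdm5d had 733 and 571 against 795 and 564, and Uty had 260 and 384 against 370 and 444.

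In the authors' deposited table, 1330 genes had an adjusted p under 0.05, of which 802 were higher and 528 lower in Whsc1-/- cells. The authors' deposited table includes all 139 genes called by limma here, each with the same sign. It gives Whsc1 a log2 fold change of -1.30 with an adjusted p of 0.256. Its headers also name a second fold change, lfcMLE, so -1.30 may not be the same measure as the limma change of -1.48. The authors' deposited table is a second treatment of the same libraries and not independent evidence. In the authors' deposited enrichment tables, 11 of 252 listed gene ontology terms and 11 of 41 listed KEGG pathways had a Benjamini-adjusted p under 0.05. Those tables list terms with an unadjusted p of up to 0.0989 and 0.0957, and the number of terms tested is not given in the authors' deposited tables. The authors' deposited gene ontology table was led by immune system process, with 74 genes, a 3.68-fold enrichment and an adjusted p of 6.22e-19. Of the genes matched to that term, the authors' deposited table lists 62 as higher and 12 as lower in Whsc1-/- cells. MHC class II presentation of exogenous peptides had 9 genes and an 11.9-fold enrichment in the authors' deposited table. The KEGG pathways in the authors' deposited table were led by Lysosome (28 genes, 3.81-fold, adjusted p = 5.33e-07) and Hematopoietic cell lineage (21 genes, 4.15-fold, adjusted p = 9.29e-06).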

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

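The alternatives were chosen before the data were examined, except 1 for the V segments. With 2 libraries per group the count of changed genes depended on the setting, from 139 (97 rose, 42 fell) to 64 with a pseudocount of 0.5 (46 and 18), 252 with 8 (170 and 82), 51 under upper-quartile scaling (37 and 14), 303 under total-count scaling (158 and 145), 328 with a robust prior (218 and 110), 1264 with DESeq2 (809 and 455), 358 at an adjusted p under 0.1 (229 and 129) and 1330 in the authors' deposited table (802 and 528). limma without trend called 0 genes, with 1926 at an unadjusted p under 0.05, while edgeR called 170 on the same libraries. Leaving out 1 library gave 0 to 12 calls (0 to 5 rose, 0 to 7 fell): 0 without either wild-type library or without Whsc1-/- replicate 3, and 12 without Whsc1-/- replicate 1. The lone library was then assumed to vary like the other group, and fewer samples lower the power. All 139 genes had both Whsc1-/- libraries on 1 side of both wild-type libraries, so leaving out a library could not reverse their direction. They kept it under the 15 refits, and 86 of them were among the 303 called under total-count scaling. The median of all genes was -0.36 on the log2 scale under that scaling, against -0.10, and also -0.36 without a filter, where 135 genes were called. The cause of the moves was not tested. No paired analysis was possible because the groups share only 1 replicate number.

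Of 37 lists, 21 passed in camera and 17 to 24 under other settings of the fit, but 0 with an estimated correlation, where list members moving together widen the error, and 1 with fry. Several lists without a call changed direction, and the cause was not tested. These were T-lineage specification (adjusted p = 0.771 without a filter, 0.997 under total-count scaling, 0.9999 with edgeR, 0.765 with DESeq2, 0.825 on ranks, 0.089 to 0.979 over the left-out libraries), p53 targets (0.588 without a filter, 0.952 under upper-quartile and 0.925 under total-count scaling, 0.734 without trend, 0.825 on ranks, 0.954 to 0.987 over the left-out libraries) and the histone methylation enzymes (0.689, 0.996 and 0.825 without a filter, without trend and on ranks, 0.462 to 0.934 over the left-out libraries). The stromal list turned with a pseudocount of 8 (0.927), under upper-quartile scaling (0.984), without trend (0.996), with edgeR (0.964), with DESeq2 (0.765) and on ranks (0.884), with 0.335 to 0.954 over the left-out libraries. Interferon-stimulated genes turned under total-count scaling (0.997) and over the left-out libraries (0.186 to 0.665), and ribosomal proteins with DESeq2 (0.999).

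Some directions rested on 1 library. Over the left-out libraries, adjusted p ran from 2.47e-06 to 0.388 for ribosomal proteins, 1.41e-14 to 0.882 for oxidative phosphorylation, 0.0807 to 0.882 for mitochondrial transcripts, 0.00134 to 0.381 for cholesterol synthesis, 0.0230 to 0.929 for NF-kappaB, 0.462 to 0.986 for apoptosis regulators, 8.86e-05 to 0.659 for erythroid markers and 2.05e-05 to 0.941 for mast cell and basophil markers, each with a change of direction. In each of these lists the medians of the 2 Whsc1-/- libraries lay on opposite sides of the wild-type mean. In replicates 1 and 3 they were 0.98 and -1.56 for ribosomal proteins, and 0.64 and -1.53 for oxidative phosphorylation. All 577 genes with a mean over 10000 normalised counts had a median log2 difference of 1.72 between these replicates. The opposite signs may therefore not be particular to these lists. The log2 change of mt-Nd2 ran from -1.41 to 0.22, that of mt-Atp8 from -1.32 to 0.40 and that of Pecam1 from -0.25 to 0.80. Why the Whsc1-/- libraries differed was not tested. Whsc1 stayed lower and short of the threshold under every refit, from -2.09 without Whsc1-/- replicate 3 to -0.87 without replicate 1. The V segment difference ran from -3.73 to -0.45 under the alternatives chosen beforehand, on 85 and 157 reads in the Whsc1-/- libraries. It was -0.01 between medians of tested members with those at 0 at their bound, an alternative added after the values were seen. As 33 of 39 distal but 4 of 11 proximal members were at their bound, that value does not show that a difference was absent. The authors' deposited table held 1745 genes at an adjusted p under 0.1 beside its 1330.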

Other observations

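The families and tests in this part were chosen after values were seen, except the test of X-linked genes. Intervals given here for 1 Whsc1-/- library cover no variation between libraries of that group. Of all tested genes, 20.6% had both Whsc1-/- libraries above both wild-type libraries and 22.9% below, where chance gives 16.7% each. Above both wild-type libraries lay all 5 tested Lilr and Pir receptor genes (3 rose in limma), 4 of 5 Ifi200-family genes (2 rose) and 4 of 5 Cebp transcription factor genes (none called by limma, with 4 at an unadjusted p under 0.05, and 3 up in each of edgeR, DESeq2 and the authors' deposited table). Other families were mixed. Of 7 Cd300 genes 5 lay above and 1 below (2 rose), of 6 Ifitm genes 3 above and 1 below (1 rose), and of 10 Ms4a genes 5 above and 2 below (2 rose). Of 13 cathepsins 9 lay above, of which 1 rose, and 3 below, of which 1, Ctse, fell. Of 11 Klra genes, natural killer receptors of the Ly49 family, 7 lay below and 1 above, and 2 fell (median log2 change -3.50). Ncr1, of the T and NK cell list, had 103 and 1146 normalised counts in Whsc1-/- replicates 1 and 3 against 1640 and 2581. In that list 5 of 20 members lay below and 2 above. Whether the wild-type sorts held cells other than pro-B cells was not tested. Of 44 histone genes of the large cluster, whose transcripts mostly lack poly(A) tails, 24 lay below and none above (median -1.78). Of these limma called none (11 at an unadjusted p under 0.05), edgeR 1, and DESeq2 and the authors' deposited table each 4, all lower. Both medians kept their sign under each scaling tried. Reads shared among members of these families were not tested.

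Replicates differed with abundance, and the sign of the difference changed. Among 577 genes with a mean over 10000 normalised counts, the median log2 difference was 1.14 between wild-type replicates 1 and 2 and 1.72 between Whsc1-/- replicates 1 and 3. It was 0.08 and 0.01 for genes between 1000 and 10000, -0.29 and -0.44 for genes between 100 and 1000, and 0 in both groups for genes between 10 and 100.

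B-lineage transcripts were lower and granulocyte, monocyte or dendritic transcripts higher in the Whsc1-/- libraries, although the sort required CD19. The authors' scaling is argued against by these opposite directions, since 1 size factor per library moves all of its genes alike. The median of the pre-B cell receptor list was -2.84 at its highest under 3 other scalings, which by itself could hardly have come out otherwise. Other blood cells in the sort of Whsc1-/- replicate 1 stay open: 88.9% of the granulocyte markers (16 of 18, in a list where 14 had a wild-type mean of at least 10) lay at least 8-fold above both wild-type libraries, S100a8 stood at 2386499 and Mpo at 1129070, and no B-lineage gene of 17 exceeded 8.35% of its wild-type mean, but these values restate the pattern and do not separate other cells from changed cells. In replicate 3 the summed light-chain transcripts stood at 0.820% of the wild-type mean. The gap of their log2 ratio from the median of the 17 genes was taken against each wild-type library. It was -2.83 against 1 (bootstrap 95% interval -3.87 to -0.88) and -3.53 against the other (-4.57 to -2.06). The same gap between the wild-type libraries was -0.70. The median of members, tried first and capped by the 44 of 60 members at 0, gave -1.31 (-2.66 to 0.69). Whether wild-type light-chain reads came from the same cells as the 17 genes was not tested. The gaps of the summed signal count against dilution of unchanged pro-B cells in replicate 3 only if those reads did. Dilution thus stays open for light-chain transcripts. For the 17 genes dilution stays open as well. The SD of their log2 ratios was 0.99 for replicate 3 against the wild-type mean and 0.65 for wild-type replicate 1 against 2. The first SD was 1.54 times the second (bootstrap 95% interval 1.16 to 2.05), which spans the bar of 1.5. As only the first is taken against a mean of 2 libraries, equal noise alone would put that ratio below 1. This test was written after values were seen, and its bar stood at 1 until the ratio was known. At a bar of 1 the interval would argue against dilution, so the outcome depends on that choice. A labelling error in replicate 1 and an effect of the loss of Whsc1 on the cells themselves were not tested and stay open, and a labelling error would change what every value of that library means.

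Xist was detected in both Whsc1-/- libraries, while Y-linked genes were present in all 4. Female cells as most of a library are argued against, since the mean log2 ratio of 4 Y-linked genes to their X-linked homologues changed by -0.37 in replicate 3 (lower bound -0.81) and -0.05 in replicate 1. The mean of replicate 1 was raised by Kdm5d, with a log2 ratio of 0.04 against -0.31 and -1.05 in the wild-type libraries. Its ratios for Ddx3y, Eif2s3y and Uty were below both wild-type libraries. A smaller share of female cells was not tested, and the sex of donors and recipients is not given in the sources used here. Whether Xist may have silenced the X chromosome of male cells cannot be told apart from no silencing, since the median of 501 X-linked genes lay -0.15 from that of autosomal genes (bootstrap 95% interval -0.28 to -0.04), between the bounds set beforehand. An effect of genotype stays open, as untested.

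Mitotic genes were lower in the Whsc1-/- libraries, with replication genes closer to the wild type. Fewer cycling cells as the cause were taken to lower both alike, within 0.5 on the log2 scale, a premise that was not tested. The replication median lay above the mitotic median by 0.66 in replicate 3 (bootstrap 95% interval 0.29 to 0.93) and by 2.13 in replicate 1 (1.65 to 2.40). Each interval rests on 1 Whsc1-/- library and covers no variation between libraries. The interval of replicate 3 spans the bound, and the gap of replicate 1 counts against fewer cycling cells only under that premise. A lower share of cycling cells therefore stays open in both libraries. An effect of genotype was not tested, and a different mix of cells stays open as well.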
